A study of Mus musculus with 9 samples.

How the data were processed

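RNA was sequenced from 9 mouse tissue samples collected after talc had been placed in the left thoracic cavity, 3 each at day 0, day 3 and day 9. Per the labels, day 0 means 30 min after talc. RNA was isolated with a column kit for small samples, mRNA was selected by its poly(A) tail, and libraries were made with a ligation-based kit. No library strand is stated in the sources used here, so reads of overlapping or antisense genes may have been counted for either gene. The aligner and the counting program are not given in the sources used here. The labels do not say that the replicates of a day came from separate mice. If they did not, the p-values measure only the spread between these samples, which may be technical.

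The authors deposited 1 table for the whole series with 25652 genes, of which 7737 had no read in any library. It holds, per library, the count of reads per gene and a signal in CPM, counts scaled to a common library size, which the authors had divided by an effective library size. It also holds the authors' log2 fold changes between days and their FDR-adjusted p-value for each gene. The counts were used for every test and every CPM value given here, and the authors' CPM were used only to recover their scale factors. Columns of the authors' CPM summed to between 874101 and 1.10315e+06. The 9 factors recovered from them differed from the TMM factors computed here by at most 0.00329. The submitters' processing notes name GRCm38 and mm10, but only 567 of the 25597 gene identifiers found in GENCODE M21 had the same start there, and 564 the same chromosome, start and end. No coordinates are therefore given, and genes are identified by the symbols in the authors' table. 3 lines of the table were emptied and were not used here. Reads of close paralogs such as Saa3, Serpina3m and Clca3a2 may be shared with their relatives.

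Library totals were between 12769059 and 18701063 counts. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules. The floor used for a gene with no or few reads was 3 counts over the group. Within each day, pairs of libraries were compared by a chi-square over genes. Its value per degree of freedom was between 8.61 and 153, so no pair agreed within sampling noise and every library was counted once.

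Genes were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The filterByExpr function by day left 14794 genes. TMM factors were applied, and the edgeR quasi-likelihood F test was fitted to all 9 libraries with 1 mean per day, which left 6 residual degrees of freedom. The median prior degrees of freedom were 2.62. Days 3 and 9 were each compared with day 0, day 9 was compared with day 3, and 1 F test asked for a difference between any days. All tests were two-sided. A gene passed when its Benjamini-Hochberg adjusted p over all tested genes was under 0.05, and "adjusted p" below means this value. SE of a log2 fold change is the standard error, and day means of CPM carry the SD over 3 libraries. The groups, tests, gene lists, rule for named genes and first set of alternatives were fixed before the data were examined.

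The 39 gene lists held 478 entries, of which 476 were in the table. They covered macrophage, monocyte, alveolar macrophage, large cavity macrophage, scar-associated macrophage, alternative macrophage activation, neutrophil, T cell, B and plasma cell, NK and cytotoxic cell, dendritic cell, and eosinophil and mast cell genes. They also covered fibroblast, myofibroblast and smooth muscle, mesothelial, endothelium, alveolar type 2, alveolar type 1, airway epithelium, skeletal muscle, cardiac muscle, adipocyte, cartilage and bone, and erythroid genes. Lists of processes were inflammatory cytokines, neutrophil chemokines, monocyte chemokines and growth factors, extracellular matrix, proliferation, coagulation and fibrinolysis, immediate early genes, interferon response, class II antigen presentation, giant cell and osteoclast fusion, wound growth factors, glycolysis and hypoxia, clock output, steroid and stress response, and sex-linked genes. Some genes stand in more than 1 list, such as Fn1 in the monocyte and matrix lists and F10 in the large cavity macrophage and coagulation lists. These are bulk libraries, so a list shows which transcripts moved and not how many cells of a type were present. Each list was tested with camera on log2 CPM (prior count 2) with its preset correlation of 0.01, adjusted over the 39 lists of a comparison. The same test was run with a correlation estimated per list, which for most lists was far above the preset value, and no list passed in any comparison with it, where 2, 5 and 4 lists had an unadjusted p under 0.05 at day 3 against day 0, day 9 against day 0 and day 9 against day 3. A list is said below to have been called when it passed with the preset correlation. Fry was run as well. It asks whether the genes of a list moved on balance in 1 direction, and does not compare them with other genes, and it called 15, 13 and 5 lists in the same order.

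Named genes followed a rule. 12 anchor genes were fixed for every comparison whatever their result, of which 1 is not reported here and does not enter the counts of named results. To these were added the 5 genes with the largest fold change in each direction among those past the threshold, with a mean of at least 10 CPM in the higher day and no overlap between libraries, clone names and pseudogenes left out. From each described list up to 4 members past the threshold with the largest fold change and at least 1 CPM could be named. The set of list members was first longer and was shortened after the fits without each library had been seen. Members whose result rested on single libraries made up most of those dropped. The named genes are therefore steadier than called genes in general. Of the 106 named results past the threshold, 86 stayed past it without any 1 library, against 2528 of the 6766 results of all called genes (37.4%).

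The steps were tested on simulated data with 100 genes changed at each fold. For day 3 against day 0, with 14620 genes, 40% of 2-fold and 85% of 4-fold changes were recovered, with 7 false calls among 14400 unchanged genes. For day 9 against day 0, with 14620 genes, the shares were 34% and 78%, with 10 false calls. For day 9 against day 3, with 14640 genes, they were 40% and 78%, with 7 false calls. No gene was called where none had been changed.

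The first set of alternatives held RLE size factors, library size without TMM, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM in 3 libraries, the replicate number as a block, only the 6 libraries compared, a fold threshold, and leaving out each library. Other pseudocounts had been foreseen for data without counts and were not run, because counts were used. Chosen after seeing the data were robust dispersions, the mean of the alveolar type 2, cartilage and bone or skeletal muscle list as a covariate, the fit without day 0 replicate 3 and day 3 replicate 3, and recounting the time patterns under each setting. Replicate numbers are not said to pair samples, so the block was used only as an alternative. Libraries of different days were also correlated across genes, as deviations of log2 CPM from their day means. Pairs of the same number gave -0.248 to 0.472, and pairs of different numbers -0.596 to 0.516.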

Results

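Talc in the pleural space makes the lung surface adhere to the chest wall, and the study asked how macrophages gather on the injured surface while adhesions form. Wild-type mice received 200 µL of a talc suspension at 2.0 g/kg through the diaphragm into the left thoracic cavity, and tissue was taken 30 min later (day 0), at day 3 and at day 9. Each day had 3 libraries, numbered 1, 2 and 3 at day 0 and 1, 3 and 4 at days 3 and 9. Day 0 is the earliest time after talc and not an untreated control, and no untreated or vehicle mice were analysed here. Time since talc and time since the injection procedure therefore run together in every comparison. The labels describe the tissue in different ways, once as adhesion tissue between lung and chest wall and once as left lung tissue attached to the chest. Totals were 18004052, 16685482 and 17665356 counts at day 0, 17089112, 14841140 and 14515737 at day 3, and 13888015, 18701063 and 12769059 at day 9, each in the order of the replicate numbers.

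Muscle transcripts were abundant in every library. The 14 skeletal muscle list genes took between 6.60% and 13% of all counts, and the most abundant gene of every library was Myh4, a fast muscle myosin, or mt-Co1, a mitochondrial gene. Lung genes differed between libraries of the same day. The mean of the alveolar type 2 list was 7.66 to 7.75 log2 CPM at day 0, 3.20, 7.97 and 2.39 in day 3 replicates 1, 3 and 4, and 5.29, 6.84 and 7.0 in day 9 replicates 1, 3 and 4. Sftpc, the surfactant protein C gene of these cells, was at 3157 CPM in day 3 replicate 3 and at 51.6 and 24.0 CPM in replicates 1 and 4. The airway epithelium list had the same spread, with 1.47, 5.65 and 1.07 log2 CPM at day 3. The cartilage and bone list stood at 5.42 in day 0 replicate 3, 6.28 in day 3 replicate 1 and 6.78 in day 9 replicate 1, and between 1.31 and 3.77 in the other 6 libraries. The cardiac muscle list was at 6.0 in day 0 replicate 3 and at 3.03 or below elsewhere. Ddx3y, a gene of the Y chromosome, was at 67.2 to 91.0 CPM in all 9 libraries. Correlations of log2 CPM between libraries of 1 day, across genes, were 0.974 to 0.988 at day 0, 0.895 to 0.953 at day 3 and 0.961 to 0.983 at day 9.

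**Figure D1:**
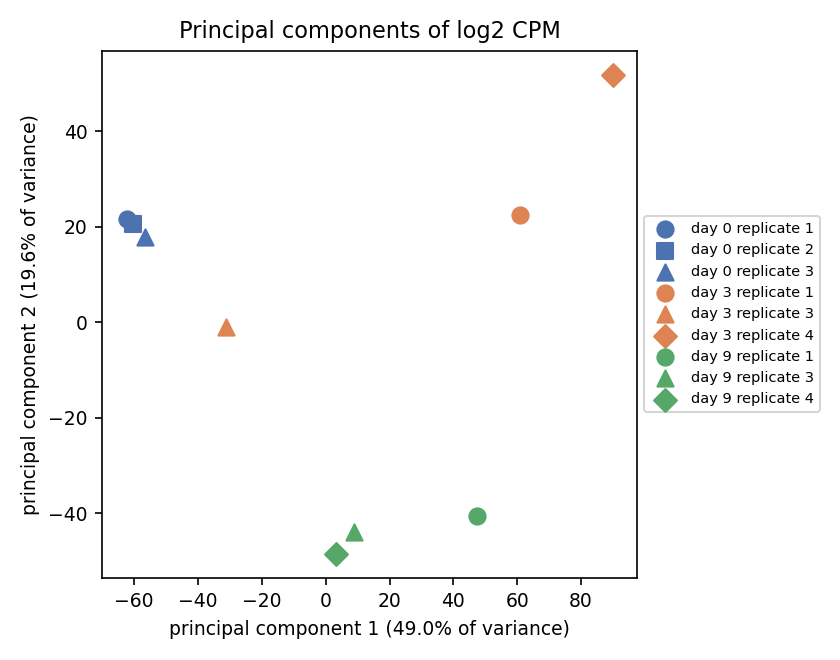
The 9 libraries on the first 2 principal components of log2 CPM, which hold 49.0% and 19.6% of the variance, coloured by day and numbered by replicate. Day 3 replicate 3 sits at -31.1 on the first axis, while the other day 3 libraries sit at 61.0 and 89.9 and the day 0 libraries between -62.3 and -56.6.

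At day 3, macrophage and inflammatory transcripts were far above their level at 30 min. Adgre1, which encodes the macrophage marker F4/80, was 4.91-fold higher (15.2 ± 1.31 against 74.5 ± 15.9 CPM, SD, n = 3), and Cd68, a lysosomal protein of macrophages, was 5.85-fold higher (20.3 ± 0.876 against 119 ± 25.4 CPM). Spp1, encoding osteopontin, rose 6.45-fold to 1250 ± 427 CPM, and Arg1, the arginase of alternatively activated macrophages, went from 0.538 ± 0.361 to 367 ± 113 CPM. The chemokine Ccl2, which draws monocytes, rose 17.0-fold, and the cytokine Il1b 6.87-fold. Immediate early transcription factors were lower, Egr1 6.09-fold and Fosb 9.34-fold. Arg1 passed with edgeR (adjusted p = 0.00341) but gave 0.0828 with limma-voom and 0.0632 with the replicate number as a block, within 0.000787 to 0.0828 over all alternatives, and Fosb gave 0.053 with the alveolar type 2 covariate, within 5.04e-09 to 0.0539. The log2 fold change of Fosb was -3.22, and -2.96 with that covariate. The main fibrillar collagen gene Col1a1 stood at 3356 ± 700 CPM at day 0 and 3284 ± 2228 CPM at day 3 (adjusted p = 0.968), and its sign turned without day 0 replicate 1 or 2 or day 3 replicate 3 or 4, over a range from -0.75 to 0.21 on the log2 scale.

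Among macrophage genes, 13 of 16 rose at day 3 and none fell, or 15 adjusted over the list alone, with a median log2 fold change of 2.06. They included Cd14, a receptor for bacterial lipopolysaccharide (7.04-fold), and Fcgr1, the high-affinity IgG receptor (16.5-fold). The list passed with adjusted p = 3.21e-09, and adjusted p = 0.354 with an estimated correlation. Of 15 genes of scar-associated macrophages 10 rose, the same 10 adjusted over the list alone, among them Trem2, a lipid-sensing receptor (15.5-fold), the glycoprotein gene Gpnmb (16.2-fold) and Mmp12, the macrophage elastase (41.3-fold). Its test gave adjusted p = 2.07e-05, and adjusted p = 0.354 with an estimated correlation. In the monocyte list 7 of 15 genes rose and 1 fell, the same adjusted over the list alone. Its receptor gene Ccr2 was 5.21-fold higher, and the list gave adjusted p = 0.0131, but 0.111 without day 3 replicate 3, within a range of 0.00085 to 0.354 over all alternatives and with adjusted p = 0.354 with an estimated correlation. Of 12 genes of alternative activation 6 rose and 1 fell, also adjusted over the list alone, with Ccl24, an eosinophil chemokine, 29.8-fold higher (adjusted p of the list = 0.01, and adjusted p = 0.49 with an estimated correlation).

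Many genes for signals that recruit leukocytes were higher at day 3 as well, while others were lower or did not pass. Of 12 monocyte chemokines and growth factors, 9 rose and 2 fell, or 9 and 3 adjusted over the list alone, with Ccl7 at 16.7-fold and Ccl8 at 19.1-fold (adjusted p = 0.000169, and adjusted p = 0.354 with an estimated correlation). Of 7 neutrophil chemokines 4 rose, or 5 adjusted over the list alone. Cxcl5 was 116-fold and Cxcl3 79.3-fold higher, from 0.277 ± 0.0960 and 0.173 ± 0.176 CPM at day 0. The list gave adjusted p = 0.0111, but 0.0608 and 0.102 without day 3 replicate 1 or 3, within 0.00163 to 0.485 over all alternatives and with adjusted p = 0.485 with an estimated correlation. Inflammatory cytokine genes rose in 8 of 15 cases, or 9 with 1 lower adjusted over the list alone, and Il1rn, the natural blocker of the interleukin 1 receptor, was 12.3-fold higher (adjusted p = 0.00397, and adjusted p = 0.49 with an estimated correlation). In the coagulation and fibrinolysis list 11 of 17 genes rose, the same 11 adjusted over the list alone. They included the clotting factors F10 (11.5-fold) and F7 (7.22-fold), and Plau, the protease urokinase (3.00-fold). The list gave adjusted p = 0.000169, and adjusted p = 0.354 with an estimated correlation. The call of Plau ended without day 0 replicate 1 (0.0654) or replicate 2 (0.0643), within a range over all alternatives of 9.74e-05 to 0.152. Interferon response genes rose in 7 of 12 cases, also adjusted over the list alone, with Oas1a 4.65-fold higher (adjusted p = 0.00298, and adjusted p = 0.485 with an estimated correlation). Proliferation genes rose in 5 of 14 cases, or 9 adjusted over the list alone, with the cell cycle kinase Cdk1 2.26-fold higher (adjusted p = 0.00154, and adjusted p = 0.524 with an estimated correlation).

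Other large changes at day 3 were in the acute-phase gene Saa3 (242-fold higher, 587 ± 82.4 CPM at day 3), Acod1, which makes itaconate in activated macrophages (143-fold), and Chrng, the embryonic gamma subunit of the muscle acetylcholine receptor. Chrng had 84.8 CPM in day 3 replicate 4 alone and a mean of 28.7 ± 48.6 CPM. Its adjusted p of 0.0492 rose above 0.05 without any library except day 3 replicates 1 and 3, to 0.177 without day 3 replicate 4, and was between 0.0109 and 0.664 over all alternatives. The matrix protease inhibitor Timp1 rose 16.5-fold and the fibronectin gene Fn1 3.10-fold. They were among 5 matrix genes that rose, with 2 that fell, of 23, the same adjusted over the list alone, and the list was not called (adjusted p = 0.754). Fasn, the fatty acid synthase gene, fell 5.88-fold, Kcng4, a potassium channel subunit, 8.02-fold, and Mettl21c, a methyltransferase gene of muscle, 6.47-fold.

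The immediate early list fell most clearly, with 8 of 12 genes lower and none higher, or 8 lower and 1 higher adjusted over the list alone. Fos was 5.40-fold and Nr4a1 4.68-fold lower (adjusted p of the list = 2.07e-05, and adjusted p = 0.354 with an estimated correlation). In the myofibroblast and smooth muscle list 5 of 11 genes fell and 1 rose, or 6 and 1 adjusted over the list alone. Myh11, the smooth muscle myosin, was 2.06-fold lower, while Acta2, the smooth muscle actin used as a myofibroblast marker, stood at 116 ± 16.0 and 115 ± 20 CPM (adjusted p = 0.965). The list gave adjusted p = 0.00119, and adjusted p = 0.354 with an estimated correlation. Without day 0 replicate 1 or day 3 replicate 3 the sign of Acta2 turned, within -0.16 to 0.09 on the log2 scale. T cell genes fell in 3 of 12 cases, or 9 adjusted over the list alone (adjusted p = 5.13e-05, and adjusted p = 0.354 with an estimated correlation). B and plasma cell genes fell in 3 of 10 cases, or 5 adjusted over the list alone, with Fcrla 5.10-fold lower, and NK and cytotoxic cell genes in 1 of 8, the same adjusted over the list alone. These lists gave adjusted p = 0.00128 and 0.00341, and adjusted p = 0.524 and 0.49 with an estimated correlation. The day 3 libraries spread from 0.885 to 3.31 log2 CPM in the mean of the B and plasma cell list.

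Lung epithelial, endothelial, muscle and adipocyte lists were lower on average at day 3, where the alveolar type 2 mean was 3.20, 7.97 and 2.39 log2 CPM. In this comparison 0 of 12 alveolar type 2 genes passed, with a median log2 fold change of -1.28 in the gene fits. The list test is run on log2 CPM, where the mean change was -3.2, and gave adjusted p = 0.000578. Of 12 alveolar type 1 genes 1 rose against a median of -1.51 (adjusted p = 0.00282), 1 of 10 airway genes fell (0.00397), and 1 of 14 endothelial genes fell (0.00211), which was Plvap, a protein of capillary pores (2.02-fold). Adjusted over the list alone, 0, 1, 1 and 0 genes of these 4 lists passed, and each had adjusted p = 0.524 with an estimated correlation. The call of Plvap ended without any day 0 library, day 3 replicate 1 or 4, or day 9 replicate 3, with adjusted p up to 0.116, and its adjusted p was 0.0014 to 0.17 over all alternatives. With the alveolar type 2 mean as a covariate the type 1 and airway lists were no longer called (adjusted p = 0.27 and 0.945, within 1.23e-05 to 0.524 and 0.00016 to 0.945 over all alternatives). The mean change of the airway list in log2 CPM went from -2.65 to 0.12. The type 2 list cannot be tested with its own mean as the covariate, which sets its change to 0. The same covariate ended the calls of the endothelial, B and plasma cell, NK, erythroid and class II lists (adjusted p = 0.3, 0.0753, 0.163, 0.192 and 0.163). Over all alternatives their adjusted p lay within 0.000129 to 0.524, 0.000273 to 0.524, 0.00209 to 0.49, 0.00122 to 0.524 and 0.00434 to 0.524. Skeletal muscle genes fell in 2 of 14 cases, also adjusted over the list alone (adjusted p = 0.00423, but 0.316 without day 3 replicate 3, within 5.05e-07 to 0.524), and erythroid genes in 0 of 7, also adjusted over the list alone (0.0046). Of the 7 class II antigen presentation genes 1 fell, or 4 adjusted over the list alone (0.0115, but 0.0963 without day 3 replicate 1). Each of these 3 lists had adjusted p = 0.524 with an estimated correlation. Sftpc averaged 2851 ± 165 CPM at day 0 and 1078 ± 1801 CPM at day 3 (adjusted p = 0.525), and was lower by -6.30 on the log2 scale without day 3 replicate 3 (0.00125, within 0.00125 to 0.726 over all alternatives). Msln, the mesothelial marker mesothelin, was at 9.47 ± 8.89 and 15.1 ± 13 CPM (adjusted p = 0.682), and its sign turned without day 3 replicate 4, within -0.27 to 1.77 on the log2 scale.

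Of 14794 genes tested, 1904 were higher and 486 lower at day 3 than at day 0, of which 724 and 201 changed at least 2-fold. The authors' deposited table calls 1178 and 544 genes at the same threshold, of which 1047 and 278 are shared. The fit of 9 libraries uses 1 spread per gene for all days. A fit of only the 6 libraries of days 0 and 3 called 924 genes in both directions together. Without 1 of the day 0 libraries or day 9 replicate 1 or 4, between 687 and 1264 genes were higher, and without 1 of the day 0 libraries or day 9 replicate 3, between 131 and 292 were lower. Without day 3 replicate 3, 2624 genes were lower, and with the replicate number as a block 186 genes were higher and 28 lower. That block ended 38 of the 123 named results of all comparisons.

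**Figure D2:**
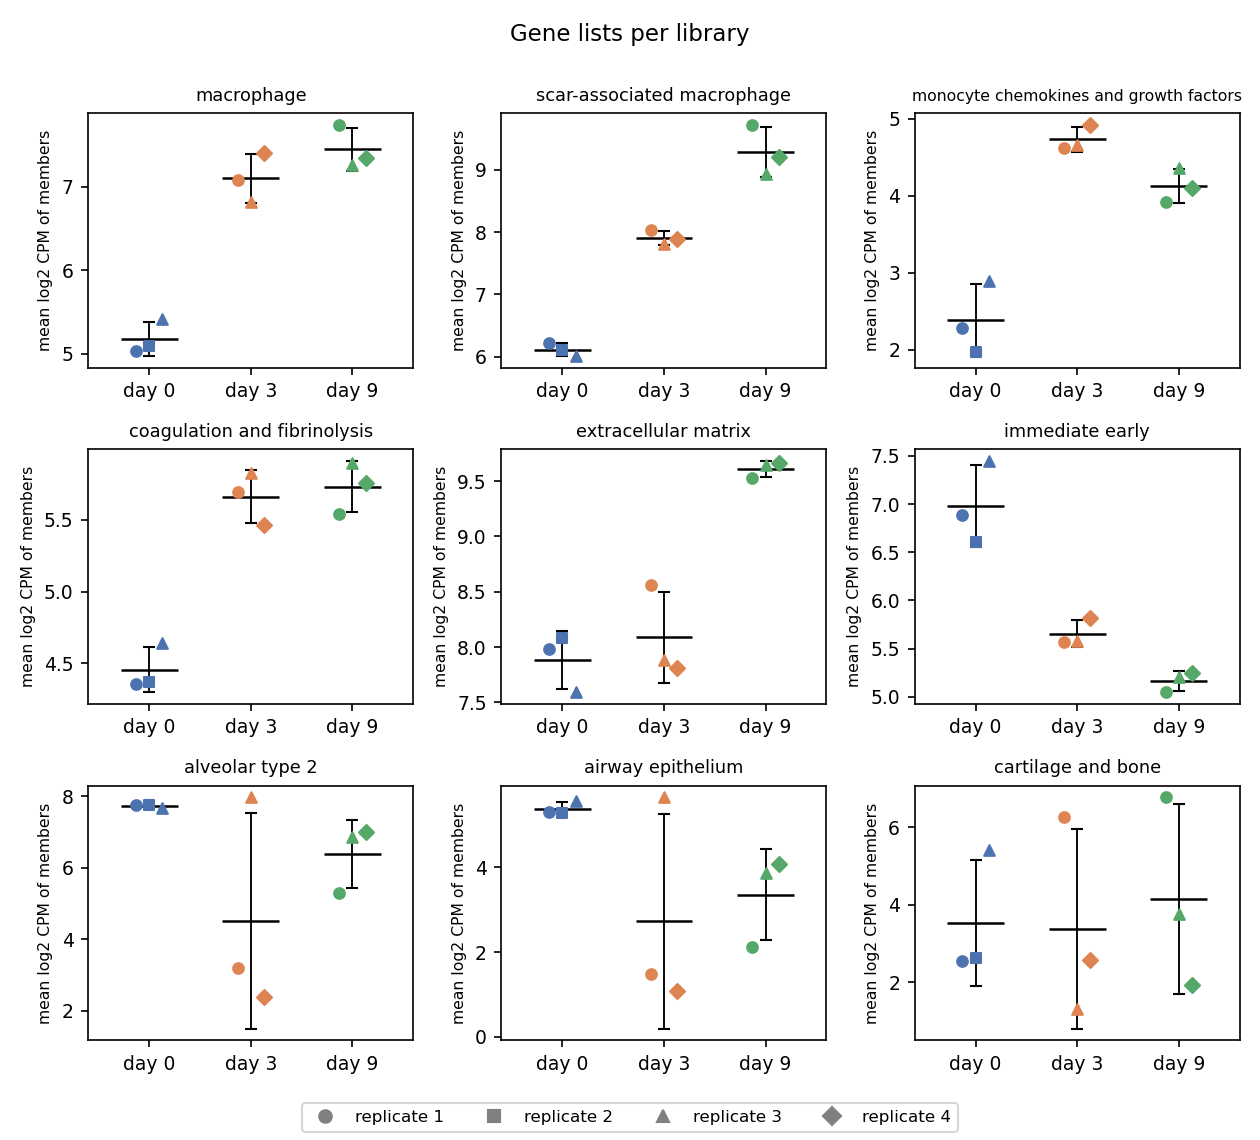
Mean log2 CPM of the members of gene lists in each library, with 1 point per library, shaped by replicate, and a bar and error bar for the mean and SD of each day (n = 3). The macrophage list has means of 5.18, 7.10 and 7.45 at days 0, 3 and 9, and the matrix list 7.89, 8.09 and 9.61.

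At day 9 the macrophage transcripts were still raised and matrix transcripts had risen with them. Adgre1 was 7.87-fold above day 0 (119 ± 30.6 CPM), Cd68 13.5-fold (274 ± 108 CPM) and Spp1 10.1-fold (1963 ± 697 CPM). Genes of scar-associated macrophages were among the largest changes, with Mmp12 409-fold higher (1001 ± 215 CPM) and Gpnmb 323-fold higher (3154 ± 1878 CPM). Col3a1, the type III collagen of early scar, rose 5.91-fold to 10720 ± 351 CPM, and Fn1 6.18-fold to 3109 ± 746 CPM. Col1a1 was at 8699 ± 823 CPM, a 2.59-fold difference that did not pass (adjusted p = 0.0544). It passed without any of the 3 day 3 libraries (0.00367, 0.02 and 0.0371 without replicates 1, 3 and 4) and lay within 0.00127 to 0.163 over all alternatives.

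Of 16 macrophage genes 15 rose, the same 15 adjusted over the list alone, with Fcgr1 8.52-fold higher (adjusted p = 2.29e-11, and adjusted p = 0.304 with an estimated correlation). Of 15 scar-associated macrophage genes 13 rose, or 14 adjusted over the list alone, with a median of 2.44. Trem2 was 51.6-fold and Lgals3, which encodes galectin 3, 21.6-fold higher (adjusted p of the list = 1.05e-10, and adjusted p = 0.304 with an estimated correlation). In the matrix list 21 of 23 genes rose, or 22 adjusted over the list alone, with a median of 1.45, among them Cthrc1, a marker of collagen-producing fibroblasts (9.77-fold), and Timp1 (8.27-fold). The list gave adjusted p = 1.84e-11, and adjusted p = 0.333 with an estimated correlation. Of 15 fibroblast genes 4 rose, or 5 adjusted over the list alone, including Dpt, a collagen-binding matrix protein (3.69-fold), and the surface protein Thy1 (2.66-fold). That list was not called (adjusted p = 0.494), with a median of 0.07 and a mean of -0.03. Of 15 wound growth factors 6 rose and 2 fell, or 8 and 3 adjusted over the list alone, with Igf1 3.00-fold and Tgfb2 2.29-fold higher, and the list was not called (0.378).

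Coagulation genes were higher in 11 of 17 cases, also adjusted over the list alone, with F7 15.9-fold, F10 7.74-fold and Plau 5.23-fold above day 0 (adjusted p = 3.42e-05, and adjusted p = 0.271 with an estimated correlation). Interferon response genes rose in 8 of 12 cases, or 10 adjusted over the list alone, with Oas1a 5.51-fold higher (adjusted p = 0.000133, and adjusted p = 0.333 with an estimated correlation). Of 12 monocyte chemokines and growth factors 8 rose, or 9 with 1 lower adjusted over the list alone, with Ccl8 13-fold and Ccl2 3.62-fold higher (adjusted p of the list = 0.000505, and adjusted p = 0.432 with an estimated correlation). The call of Ccl2 ended without day 0 replicate 1 (0.0713) or day 9 replicate 4 (0.0557), within 0.000142 to 0.0713 over all alternatives. Of 15 inflammatory cytokine genes 6 rose, or 6 with 1 lower adjusted over the list alone, with a median log2 fold change of 0.006. Of 7 neutrophil chemokines 2 rose, also adjusted over the list alone, with a median of 0.12. Neither list was called (adjusted p = 0.149 and 0.262). Among their genes, Il1rn was 21.7-fold, Cxcl5 45.4-fold and Il1b 2.70-fold higher. Il1b lost its call without any day 0 library, day 3 replicate 1, or day 9 replicate 3 or 4, with adjusted p of 0.0535 to 0.138, and lay within 0.00439 to 0.247 over all alternatives. Arg1 was at 63.0 ± 81.4 CPM, a 114-fold difference from day 0 that passed (adjusted p = 0.00593), but gave 0.219 with limma-voom and 0.0798 with the replicate number as a block, within 0.00218 to 0.219. Vsig8, which encodes an immunoglobulin-domain membrane protein, was 108-fold higher. Clca3a2 had 1071 counts at day 9 against 3 at day 0, a ratio of 386 with a 95% counting interval of 132 to 1880, and its adjusted p was 1.66e-12 to 0.106 over all alternatives, the highest with limma-voom.

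Immediate early genes were lower in 9 of 12 cases, or 10 adjusted over the list alone, with Fosb 11.3-fold, Egr1 10.9-fold, Fos 8.66-fold and Zfp36, which destabilises cytokine mRNA, 5.26-fold lower (adjusted p = 3.47e-08, and adjusted p = 0.304 with an estimated correlation). Odf3l2, a member of a family of sperm tail genes, was 9.58-fold lower. Of 14 endothelial genes 5 fell, or 8 adjusted over the list alone, with the angiopoietin receptor Tek 3.03-fold lower (adjusted p of the list = 9.29e-05, and adjusted p = 0.692 with an estimated correlation). B and plasma cell genes were lower in 5 of 10 cases, or 7 adjusted over the list alone, with Cd79a, a part of the B cell receptor, 4.07-fold lower, and the list was not called (0.0706). The calls of Tek and Cd79a ended without any library of day 0 or day 9, with adjusted p up to 0.112 and 0.0986, within 0.000768 to 0.112 and 0.000334 to 0.165 over all alternatives. Clock output genes fell in 3 of 10 cases, or 4 adjusted over the list alone (adjusted p = 0.0287, and adjusted p = 0.33 with an estimated correlation), and the call ended with the alveolar type 2 covariate (0.0758, within 0.012 to 0.33). The mean log2 fold change of the list was -0.57, and -0.47 with that covariate.

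Lung epithelial, endothelial, muscle and adipocyte lists were again lower on average, with an alveolar type 2 mean of 5.29, 6.84 and 7.0 log2 CPM at day 9, while the mesothelial and cartilage and bone lists had medians of 1.17 and 1.03. The alveolar type 2 and type 1 lists were not called (adjusted p = 0.0563 and 0.0554). Of 12 type 2 genes 1 fell, or 0 adjusted over the list alone, and of 12 type 1 genes 1 rose and 1 fell, the same adjusted over the list alone. NK and cytotoxic cell genes fell in 1 of 8 cases, the same adjusted over the list alone (adjusted p = 0.0147, and adjusted p = 0.692 with an estimated correlation). No member passed in the airway, skeletal muscle, adipocyte and erythroid lists, which were nonetheless called lower (0.0287, 0.0164, 0.0442 and 0.0197), each with adjusted p = 0.736 with an estimated correlation. Adjusted over the list alone, 0, 0, 0 and 4 of their genes passed. The airway call ended without day 9 replicate 1 (0.0767, within 0.00265 to 0.736 over all alternatives). The adipocyte call ended without day 0 replicate 3 (0.19), day 3 replicate 3 (0.0747) or day 9 replicate 3 or 4 (0.0858 and 0.131), within 2.41e-05 to 0.736. With the alveolar type 2 covariate the NK and erythroid calls ended (0.0562 and 0.112, within 0.00674 to 0.692 and 0.000328 to 0.736). Sftpc averaged 1064 ± 648 CPM (adjusted p = 0.512 against day 0). Its log2 fold change was -1.42, and -4.2 with the skeletal muscle covariate, where it passed (0.0355, within 0.0355 to 0.904 over all alternatives). Myh6, the cardiac myosin, was 88.0-fold lower (adjusted p = 0.0379), from a day 0 mean of 171 ± 280 CPM that came from day 0 replicate 3, with 494 CPM. Its adjusted p was 0.135 without that library and 0.116 to 0.124 without any day 9 library, within 0.000148 to 0.405. Of 15 mesothelial genes 1 rose, or 0 adjusted over the list alone, and the list was not called (0.368). This was Wt1, a transcription factor of mesothelium (12.4-fold), whose call ended without day 0 replicate 1 or 2, day 3 replicate 1 or any day 9 library, with adjusted p of 0.0524 to 0.127, within 0.00156 to 0.164. Msln was at 40.5 ± 45.3 CPM (adjusted p = 0.201) and Acta2 at 195 ± 69.4 CPM (0.0836, but 0.00993 without day 9 replicate 1, within 0.00993 to 0.374).

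At day 9, 2246 genes were higher and 820 lower than at day 0, 1071 and 242 of them at least 2-fold. The authors' deposited table calls 1521 and 724, of which 1415 and 422 are shared. A fit of only the 6 libraries of days 0 and 9, without the spread of day 3, called 6332 genes in both directions together. Without day 0 replicate 1 or 2 or day 9 replicate 4, between 1381 and 1485 genes were higher, and without 1 of the day 0 or day 9 libraries between 273 and 392 were lower. Without day 3 replicate 3 or 4, 2221 and 1292 genes were lower, and with the replicate number as a block 777 were higher and 123 lower.

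Between days 3 and 9, the matrix list was called higher and the steroid and stress response list lower. With an estimated correlation their adjusted p was 0.406 and 0.373. Eln, the elastin gene, was 12.4-fold higher at day 9 (141 ± 8.0 against 1755 ± 577 CPM), Tnc, the wound matrix protein tenascin C, 5.88-fold (110 ± 34.8 against 646 ± 57.5 CPM), and Postn, the fibroblast product periostin, 3.95-fold. Gpnmb rose a further 20-fold and Mmp12 9.89-fold. Ccl2 fell 4.71-fold to 14.8 ± 2.39 CPM and Ccl24 20.6-fold. Adgre1 and Spp1 were 1.60-fold and 1.57-fold higher at day 9 without passing (adjusted p = 0.0793, within 0.0154 to 0.185 over all alternatives, and 0.329), while Cd68 passed at 2.31-fold (0.0298). The call of Cd68 ended without any day 0 library, day 3 replicate 1 or day 9 replicate 4, with adjusted p of 0.0529 to 0.0647. The call of Ccl2 ended without any day 9 library (0.0519 to 0.066), and that of Ccl24 without day 9 replicate 1 or 4 (0.0628 and 0.0712). Over all alternatives these 3 genes lay within 0.000391 to 0.105, 2.8e-06 to 0.066 and 4.41e-08 to 0.0712.

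In the matrix list 18 of 23 genes rose and none fell, or 21 adjusted over the list alone, with a median of 1.48 (adjusted p = 4.65e-15, and adjusted p = 0.406 with an estimated correlation). Lum, a proteoglycan of collagen fibrils, rose 3.82-fold, and its call ended without day 9 replicate 4 (0.0626, within 3.19e-06 to 0.0639). Col1a1 was 2.65-fold higher without passing (0.0788), and passed without day 3 replicate 1 (0.00662, within 0.00341 to 0.184). Of 15 fibroblast genes 2 rose, or 3 with 1 lower adjusted over the list alone. They were Dpt (4.29-fold) and Thy1 (2.33-fold), and the list gave adjusted p = 0.0135, adjusted p = 0.373 with an estimated correlation, and 0.135 with the alveolar type 2 covariate, within 0.00696 to 0.373. Scar-associated macrophage genes rose in 7 of 15 cases, or 10 adjusted over the list alone, including Lgals3 (3.65-fold) and the lipid carrier Fabp5 (3.38-fold, with 0.0574 in the fit of only 6 libraries, within 1.45e-07 to 0.067) (adjusted p of the list = 1.78e-07, and adjusted p = 0.406 with an estimated correlation). Of 11 genes of giant cell and osteoclast fusion 4 rose, the same adjusted over the list alone. Atp6v0d2, a proton pump subunit of osteoclasts and alveolar macrophages, was 11.9-fold and the collagenolytic protease Ctsk 4.68-fold higher (adjusted p of the list = 0.0031, and adjusted p = 0.603 with an estimated correlation). The call of Ctsk ended without any day 0 or day 9 library or day 3 replicate 1, with adjusted p of 0.0521 to 0.117, within 0.000213 to 0.117. Igf1 (2.18-fold) and Tgfb2 (2.81-fold) were among 5 of 15 wound growth factors that rose, or 5 with 1 lower adjusted over the list alone, in a list that was not called (0.162). Igf1 gave 0.0592 in the fit of only 6 libraries, within 5.98e-07 to 0.0592. Of 12 T cell genes 1 rose, also adjusted over the list alone, the interleukin 7 receptor gene Il7r (6.29-fold), with a list median of 1.09 (adjusted p = 0.0037, and adjusted p = 0.586 with an estimated correlation). Class II genes had 0 of 7 past the threshold and 4 higher adjusted over the list alone (adjusted p = 0.0314, and adjusted p = 0.719 with an estimated correlation), and the call ended without day 3 replicate 1 (0.152) or day 9 replicate 1 (0.0919), within 0.011 to 0.719.

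The largest rises outside these lists were in Adamts16, a matrix protease gene (39.4-fold), Ccn3, a matricellular protein gene (13.8-fold), and Clca3a2 (14.5-fold). The call of Clca3a2 ended without day 3 replicate 4 or day 9 replicate 3 or 4 (0.0635, 0.0789 and 0.0723, within 1.54e-05 to 0.137). Of 11 steroid and stress response genes 5 fell, or 8 adjusted over the list alone, with the metallothionein gene Mt2 13.6-fold lower (adjusted p = 0.000991, and adjusted p = 0.373 with an estimated correlation). Alternative activation genes fell in 2 of 12 cases, also adjusted over the list alone, which were Ccl24 and the haemoglobin scavenger receptor Cd163 (2.97-fold) (adjusted p = 0.00196, and adjusted p = 0.586 with an estimated correlation). Arg1 was 5.80-fold lower without passing (0.124), and passed without day 9 replicate 3 (0.0211, within 0.0211 to 0.332). Cd163 gave 0.052 without day 9 replicate 4, within 7.36e-07 to 0.0692. Of 7 neutrophil chemokines 2 fell, or 3 adjusted over the list alone (adjusted p = 0.0329, and adjusted p = 0.603 with an estimated correlation), but the list gave 0.18 and 0.178 without day 3 replicate 1 or 3, within 0.00679 to 0.603. Immediate early genes fell in 3 of 12 cases, or 4 adjusted over the list alone, with Zfp36 1.94-fold lower (adjusted p of the list = 0.00971, and adjusted p = 0.612 with an estimated correlation). Zfp36 lost its call without day 0 replicate 2, day 3 replicate 1 or 4, or any day 9 library, with adjusted p of 0.051 to 0.145, within 0.00235 to 0.145.

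Single genes of uncalled lists also moved. Of 10 clock output genes 2 rose and 5 fell, the same adjusted over the list alone, and that list was not called (adjusted p = 0.108). Of 15 inflammatory cytokine genes 2 fell, or 5 with 1 higher adjusted over the list alone, and of 12 monocyte chemokines and growth factors 3 fell, or 6 with 1 higher, and neither list was called (adjusted p = 0.149 and 0.129). Of 15 monocyte genes 4 fell, or 6 with 1 higher adjusted over the list alone, with Ccr2 1.94-fold lower, and its call ended without day 9 replicate 1 or 4 (0.0598 and 0.0557, within 4.87e-05 to 0.063). In the large cavity macrophage list 1 of 12 genes rose and 3 fell, or 2 and 4 adjusted over the list alone. Gata6, the transcription factor of these cells, was 4.4-fold higher, and Prg4, the lubricating proteoglycan, 3.87-fold lower, though not without day 9 replicate 1 (0.0607, within 1.72e-05 to 0.0839). Besides Ccl24, the largest falls were in Ankrd1, a stress-induced gene of striated muscle (53.7-fold, from 661 ± 856 CPM), Serpina3m, a serine protease inhibitor gene (31.0-fold), Card14, an activator of NF-kappa-B signalling (23.3-fold), and Rrad, a small GTPase gene of muscle (17.7-fold). The call of Ankrd1 ended without any day 9 library (0.0733 to 0.079, within 2.99e-06 to 0.079). Il1b, Acta2, Plau and Msln did not pass (adjusted p = 0.0762, 0.111, 0.139 and 0.428). With the alveolar type 2 covariate Plau passed (0.00617, within 0.00617 to 0.319), with a log2 fold change of 1.27 against 0.8 without it. Il1b passed without day 3 replicate 3 (0.0427, within 0.013 to 0.175), Acta2 passed without day 9 replicate 1 (0.0221, within 0.0221 to 0.277), and the sign of Msln turned without day 9 replicate 3, within -0.01 to 2.37 on the log2 scale. Sftpc was alike on average (adjusted p = 0.996), but higher at day 9 by 4.88 on the log2 scale without day 3 replicate 3 (0.0044, within 0.0044 to 1).

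Between days 3 and 9, 768 genes rose and 542 fell, 401 and 198 at least 2-fold. The authors' deposited table calls 641 and 457, of which 505 and 315 are shared. A fit of only the 6 libraries of days 3 and 9, without the spread of day 0, called 258 genes in both directions together. Without day 0 replicate 1 or 2 or any day 9 library, between 270 and 488 genes rose, and without any day 0 or day 9 library between 85 and 352 fell. Without day 3 replicate 3, 2450 rose and 1648 fell, and with the replicate number as a block 82 rose and 45 fell.

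**Figure D3:**
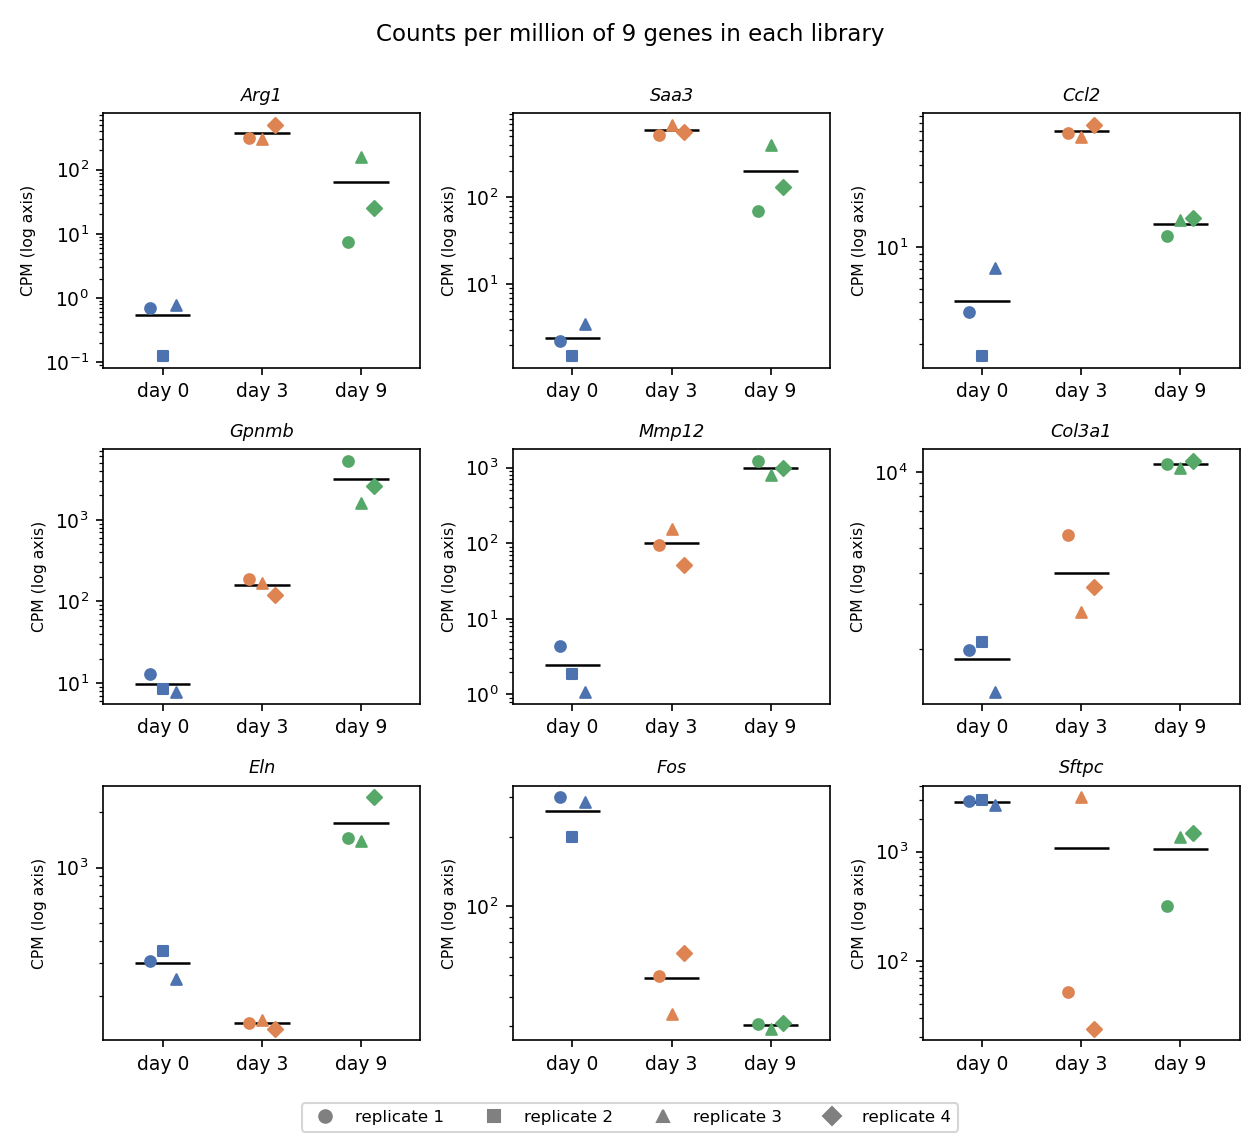
CPM of 9 named genes in each library at days 0, 3 and 9 on log axes, with 1 point per library, shaped by replicate, and a bar at the mean of each day. Ccl2 has means of 4.06, 69.6 and 14.8 CPM, and Gpnmb of 9.75, 158 and 3154 CPM.

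Across the whole course 3807 of 14794 genes (25.7%) differed between any days, with 1916 to 2382 without any day 0 or day 9 library and 7418 without day 3 replicate 3. By pairs of calls, 953 genes were higher at both later days with no call between them, such as Saa3, Acod1 and Cxcl5, and held 12 of the 16 macrophage genes and 7 of the 12 interferon genes. A late group of 603 genes was higher at day 9 than at either earlier day, with 18 of the 23 matrix genes and 7 of the 15 scar-associated macrophage genes. A transient group of 240 genes rose to day 3 and fell to day 9, such as Cxcl3, Ccl2, Ccl24, Ankrd1 and Rrad. The rule does not ask for a return to the day 0 level, and Ccl2 was still called higher at day 9 than at day 0 (adjusted p = 0.0159). In 149 genes each step was a rise, among them Mmp12, Gpnmb, Trem2 and Lgals3. The late rule does not leave out genes already higher at day 3, so these named genes also stand in the late group. Of the 15 scar-associated macrophage genes, 5 had this stepwise pattern. In the other direction 208 genes stayed lower at both later days, including Egr1, Fos, Fosb and Fasn and 7 of the 12 immediate early genes, 163 were lower at day 9 than at either earlier day, including Zfp36 and Odf3l2, and 71 fell to day 3 and rose to day 9, including Eln, Postn, Kcng4 and Mettl21c. Without 1 library the counts were 458 to 1024 (sustained higher), 224 to 1047 (late higher), 47 to 829 (transient higher), 41 to 218 (each step higher), 52 to 773 (sustained lower), 26 to 589 (late lower) and 16 to 1218 (transient lower). Most of the highest of these counts came without day 3 replicate 3, and leaving out any 1 of the 9 libraries moved at least 1 of the counts over 1.5 times. The lowest counts came without day 9 replicate 4 for the late, transient and stepwise higher and late lower groups, day 0 replicate 1 for both sustained groups and day 0 replicate 2 for the transient lower group. The stepwise group held 81 and 96 genes without day 3 replicates 1 and 4, and the late lower group 78, 40 and 53 without day 0 replicate 3 and day 9 replicates 1 and 3. The comparisons of days 3 and 9 with day 0 share the day 0 libraries, which alone ties their fold changes together. Both were higher for 1130 genes and lower for 217, against 289 and 26.9 for independent calls and 0 in 20 simulations of unchanged groups with shared libraries. Almost no gene was called in either comparison of those simulations, so their overlap was near 0 by construction. It cannot show how much overlap shared libraries give among called genes, here or for the pairs below. Their fold changes correlated across genes with r = 0.69, against a mean of 0.49 and a highest value of 0.54 in the simulations, and the covariance was 0.492 against a mean of 0.0941. The transient groups rest on a pair of comparisons that share the day 3 libraries. Their 240 and 71 genes compare with 69.8 and 25.2 for independent calls and with at most 1 in any simulation, while r was -0.28 against a mean of -0.51 and the covariance -0.151 against -0.0973. The late groups rest on a pair that shares the day 9 libraries. Their 603 and 163 genes compare with 117 and 30.0 for independent calls and with at most 1 in any simulation, while r was 0.50 against a mean of 0.50, and the covariance 0.293 against 0.0946. With 3 libraries a day none could be split between a pair of comparisons, so no overlap was tested on separate libraries and a part of each excess can come from the shared ones.

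The lists not described as called above were not called, apart from the giant cell list at day 3. At day 3 against day 0, 1 of 13 alveolar macrophage genes, 5 of 12 large cavity macrophage genes, 2 of 10 dendritic cell genes, 4 of 10 glycolysis genes and 1 of 13 neutrophil genes rose. Adjusted over the list alone these were 0, 5, 2 with 1 lower, 4 and 1. In the fibroblast list 2 of 15 rose and 1 fell, in the wound growth factor list 3 of 15 rose and 2 fell, in the clock list 1 of 10 rose and 3 fell, and in the steroid and stress list 3 of 11 rose and 1 fell. Adjusted over the list alone only the clock count differed, with 2 higher. None of 15 mesothelial, 12 eosinophil and mast cell, 9 adipocyte, 9 cartilage and bone or 4 sex-linked genes passed on either scale, and 1 of 8 cardiac genes rose, with 3 lower adjusted over the list alone. The giant cell list had 0 of 11 past the threshold, also adjusted over the list alone, and was called lower at day 3 (adjusted p = 0.0494, and adjusted p = 0.534 with an estimated correlation). That call ended without any 1 library except day 0 replicate 3 and day 3 replicate 1, with adjusted p of 0.0502 to 0.502, within 0.0113 to 0.534. Median, mean and test differed in sign for the neutrophil, eosinophil and mast cell, cartilage and bone, and wound growth factor lists at day 3 against day 0. They did so at day 9 against day 0 for the monocyte, alternative activation, fibroblast, cartilage and bone, class II and glycolysis lists. At day 9 against day 3 they did so for the alveolar macrophage, alveolar type 2, alveolar type 1, airway, B and plasma cell, NK and cytotoxic, eosinophil and mast cell, skeletal muscle, adipocyte and erythroid lists.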

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

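The covariate fits, the robust dispersions, the fit of 7 libraries without day 0 replicate 3 and day 3 replicate 3, and every recount of the time patterns were chosen only after the results had been seen, and the cause was not tested for any value below unless stated. In what follows, counts are in the order higher and lower at day 3 against day 0, then at day 9 against day 0, then at day 9 against day 3. RLE size factors, limma-voom, both other filters, robust dispersions and the cartilage covariate kept all 7 gene counts within 1.5 times. The replicate block gave 186, 28, 777, 123, 82 and 45 genes, and 749 for any days, and it uses up residual degrees of freedom. With only the 6 libraries of a comparison, 749 and 175 genes differed at day 3 from day 0, 3014 were lower at day 9 than day 0, and 167 and 91 differed between days 3 and 9. DESeq2 called 1205 genes lower at day 3 and 1512 lower at day 9 than day 0, and 1324 and 980 between days 3 and 9. Without TMM, 536 genes were lower at day 9 than day 0, and the median log2 fold change of all genes in that comparison was then 0.106. The alveolar type 2 covariate called 1028 genes higher at day 3, 912 of them among the 1904, and 2251 lower at day 9 than day 0. The muscle covariate called 1785 genes lower at day 3, 1651 lower at day 9, and 1195 and 1027 between days 3 and 9. The 7 libraries called 1756 genes lower at day 3, 1509 lower at day 9, 1817 and 1819 between days 3 and 9, and 6125 for any days. Asking for at least a 2-fold change left 724, 201, 1071, 242, 401 and 198, by its construction.

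Leaving out each library gave 687 to 2555, 131 to 2624, 1381 to 2797, 273 to 2221, 270 to 2450 and 85 to 1648 genes, and 1916 to 7418 for any days. The highest counts came without day 3 replicate 3, and the lowest without day 0 replicate 1 or day 9 replicate 4. Of the 2624 genes lower at day 3 without day 3 replicate 3, 485 were among the 486 of the full fit, and of the 687 higher without day 0 replicate 1, 686 were among the 1904. Of all called genes, 634 of 1904, 100 of 486, 1260 of 2246, 209 of 820, 247 of 768 and 78 of 542 stayed called without any 1 library.

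The list counts with camera were 10, 13, 6, 8, 6 and 4. With an estimated correlation they were 0 in each case. Correlation within the lists is not the whole reason. The fibroblast list at day 9 against day 3 had an estimated correlation of -0.00427, below the preset 0.01. Its unadjusted camera p still went from 0.00277 to 0.0187. Fry called 3 lists lower at day 3 than day 0, 11 higher and 2 lower at day 9 than day 0, and 3 higher and 2 lower at day 9 than day 3. The alveolar type 2 covariate called 5 lists lower at day 3 than day 0 and 11 lower at day 9 than day 3, with 4 in each case among the lists of the main fit. Without 1 library the counts were 8 to 11, 11 to 13, 6 to 8, 7 to 12, 5 to 9 and 3 to 9, the last with 9 without day 3 replicate 4 and 7 without day 9 replicate 3. Of 47 called list results, 38 stayed called without any 1 library. The mean change of the airway list in log2 CPM at day 3 went from -2.65 to 0.12 with the alveolar type 2 covariate (adjusted p = 0.945, within 0.00016 to 0.945).

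The time patterns moved as well, and are given in the order transient, sustained, late and stepwise higher, then transient, sustained and late lower. The replicate block gave 14, 154, 67, 4, 5, 18 and 13. DESeq2 gave 402 transient and 239 stepwise higher and 237 transient, 518 sustained and 354 late lower. Without TMM, 111 were sustained lower, and with the cartilage covariate 319. The alveolar type 2 covariate gave 117 transient higher and 118, 511 and 405 lower. The muscle covariate gave 475 transient higher, 255 transient lower and 1152 sustained lower. The 7 libraries gave 763 transient higher and 795, 450 and 524 lower. Without 1 library the patterns were 47 to 829, 458 to 1024, 224 to 1047, 41 to 218, 16 to 1218, 52 to 773 and 26 to 589.

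Of the 123 named results, 86 of 106 past the threshold stayed past it without any 1 library, and the replicate block ended 38. Signs turned only for genes that did not pass in the full fit. On the log2 scale, Col1a1 at day 3 against day 0 became 0.07 with the block, 0.60 with the muscle covariate and 0.08 with the 7 libraries, and -0.75 to 0.21 without 1 library. Acta2 there became 0.00 without TMM, 0.01 with the muscle covariate and 0.00 with the 7 libraries, and -0.16 to 0.09 without 1 library. Msln there became -0.12 with the muscle covariate, and -0.27 to 1.77 without 1 library. Msln at day 9 against day 3 was -0.01 to 2.37 without 1 library. Sftpc at day 9 against day 3 became 2.52 with limma-voom, 1.70 with the block, 0.12, 1.52 and 2.36 with the alveolar type 2, cartilage and muscle covariates, 4.81 with the 7 libraries (adjusted p = 0.00972, within 0.0044 to 1), and -0.59 to 4.88 without 1 library.

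The fits of 6 libraries and the fold threshold were not made for the test of any days, and the fit of 6 libraries gives no time pattern. Lists that were not called were followed only through the list counts. With 3 libraries a day, simulated 2-fold changes were recovered in 40%, 34% and 40% of genes, so most simulated 2-fold changes did not pass at this number of libraries. With library size alone instead of TMM, 86.2% of the genes called at day 3 were higher, and with RLE size factors 71.2%, against 79.7%.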

Other observations

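The second list of muscle genes and the list of muscle stress genes described here were written after muscle genes had been seen among the largest changes, and the tests of lung tissue amount, of alveolar cells alone and of a lower muscle share were chosen only after the result was seen. Some genes of regenerating or denervated muscle were higher at day 3 than at day 0, though the camera p of their list was 0.296 with an estimated correlation. Of 16 genes, written without those already seen, 8 rose, or 14 adjusted over the list alone, with a median log2 fold change of 2.11. They included Myog, a transcription factor of muscle differentiation (log2 fold change 4.82, SE 1.16, adjusted p = 0.026), and the acetylcholine receptor subunits Chrna1 (3.07, 0.00335) and Chrnd (4.17, 0.0236). At day 9 the median against day 0 was 0.31, and 6 genes were lower than at day 3. The list means were 3.74, 3.75 and 6.48 log2 CPM in day 3 replicates 1, 3 and 4, 2.52 to 2.81 at day 0 and 2.69 to 3.67 at day 9.

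A muscle regeneration or denervation programme is a candidate explanation for the muscle genes among the largest changes at day 3, and met its mark of at least 8 of 16 genes exactly. The camera p was 8.79e-05, and 0.296 with an estimated correlation. The count was 2 without any 1 of the day 0 libraries or day 9 replicate 4, 4 and 5 without day 9 replicates 1 and 3, 7 without day 3 replicate 4 with a median of 0.88, and 12 and 14 without day 3 replicates 1 and 3, so the count depends on single libraries. For a muscle stress programme, 3 of 14 genes rose with a median of 1.09, and its means were 8.15, 8.11 and 10.2 in the day 3 libraries. The count was 0 without any day 0 library or day 9 replicate 4, 1 without day 9 replicate 1 or 3, 2 without day 3 replicate 4 with a median of 0.15, and 4 and 8 without day 3 replicates 1 and 3. The count of 3 of 14 lay under the lower mark set for it, which by the mark as first set goes against the programme. It lies within counting error of that mark for independent genes, a condition that was added after the count had been seen. With that condition the count cannot settle it. Injury by the needle, by talc or by adhesion was not told apart, because no mice without talc were analysed here.

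The lung genes of libraries of the same day differed by several log2 units. Over the 9 libraries, the slope of the airway list on the alveolar type 2 list, both as deviations from their day mean, was 0.866 (SE 0.051). A change in alveolar epithelial cells only would leave the slope under 0.5, and is argued against by it, though the day 0 libraries hardly differed and the slope rests on day 3 (0.84) and day 9 (1.14). Different amounts of lung tissue in the libraries may account for the spread, while a loss of all lung epithelium from some pieces stays open and was not tested.

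Macrophage genes were higher at day 3 than day 0 with a median of 2.06. With the alveolar type 2 covariate the median was 1.59 (quartiles 1.22 to 1.93) and all 13 called genes stayed called, so a difference in lung content may be a part of the change but was not the whole of it at day 3. A lower share of muscle RNA would raise the genes of all other cells alike, whereas the higher of the endothelium and fibroblast medians was -0.39 against macrophage quartiles of 1.39 to 2.40. This cannot decide on the muscle share, because the endothelium list also followed lung content. Its mean change in log2 CPM was -0.87, and -0.15 with the alveolar type 2 covariate. Matrix genes were higher at day 9 than day 3 with a median of 1.48. With the cartilage covariate it was 1.49 and with the alveolar type 2 covariate 1.63, and all 18 called genes stayed called with each. For lung content this argues against it as the whole cause. The cartilage and bone mean was 3.39 ± 2.58 log2 CPM at day 3 and 4.16 ± 2.45 at day 9 (SD, n = 3). With day means so close for their spread, that covariate could hardly move the median and cannot decide on cartilage. More macrophages, more transcripts per cell, and time since the procedure apart from talc stay open for both.

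Other splits of the libraries were counted. For each comparison of days, only 1 of the 10 splits of its 6 libraries, the real one, gave as many genes, with 924, 6332 and 258 genes in fits of those 6 libraries and 0 as the highest other. A share under 0.05 cannot be reached with 10 splits. For any days, 1 of 100 drawn splits of the 9 libraries, the real one, gave as many genes, with 3807 against 589 as the highest other. That is the smallest share 100 draws can give, which makes chance unlikely for that count without excluding it.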
